A study of Homo sapiens with 3 samples.

How the data were processed

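The series measured mature miRNAs by small RNA sequencing in HCT116-R cells, a cetuximab-resistant colorectal cancer line, exposed to Pseudomonas aeruginosa-mannose sensitive hemagglutinin (PA-MSHA). Per the labels' protocols, RNA was extracted with Trizol, adaptors were ligated to the 3' and then the 5' end, and the ligated RNA was reverse transcribed and amplified by PCR. The labels assign 1 library to each of 3 doses, 0, 0.3 and 0.4 in units of 1e9 per mL.

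The authors deposited a table of 1483 mature miRNAs with 2 values per library. The first is the count of reads per miRNA, as whole numbers with no normalization, per the file headers. The second is an expression value that the authors deposited beside each count and that behaves as RPM, reads per 1000000 reads of a library total. Dividing each count by its deposited value returned a constant for each library, which put that total at 21.6 times 1000000 reads at dose 0, 21.7 times at 0.3 and 19.8 times at 0.4. The listed counts sum to 30.3%, 29.8% and 29.2% of those totals, and what else the totals hold is not given in the sources used here. Recomputed RPM matched the deposited RPM within 0.001 except for 1 entry in the library at 0.4. The submitters' processing notes name bcl2fastq 2.19.0 and the genome build GRCh38.p12. The aligner, the counting tool, the miRNA annotation version, the handling of reads that match several entries and the use of strand are not given in the sources used here. The reverse-complementary entries of the miR-7 and miR-103 loci are therefore reported as uncertain, and named entries with identical counts are pointed out. Shared sequence was not checked for other entries.

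Total counts over all listed miRNAs were 6554932 at dose 0, 6483942 at 0.3 and 5789018 at 0.4. A count of 3, taken as the floor, equals 0.425, 0.537 and 0.481 counts per 1000000 (CPM) in these libraries. Counts were scaled by the trimmed mean of M values (TMM) with edgeR 4.0.16 in R 4.3.3, which gave factors of 1.08, 0.862 and 1.08. Each log2 ratio was computed after adding a prior count of 0.5, scaled to library size. Each ratio of 2 counts has an exact conditional-binomial 95% interval for Poisson counts, and each share an exact Clopper-Pearson 95% interval. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

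With 1 library per dose, miRNAs were named by a rule of size and not by a test. A miRNA was compared when its mean over the 3 libraries was at least 10 TMM-scaled CPM, which left 343. It was called higher or lower when the ratio was at least 2-fold and the counting interval excluded 1. The comparisons were 0.3 against 0, 0.4 against 0, 0.4 against 0.3 and the overlap of the first pair. The text names the 10 most abundant miRNAs, up to 10 per direction with the largest mean log2 ratio among those called at both doses, up to 5 per direction between the treated doses, members of the 17 fixed lists, and miR-7-5p, added by name. The grouping, comparisons, filter, naming rule, lists and most alternatives were fixed before the data were examined. Any other named miRNA was chosen after its values were seen.

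The 17 lists were the let-7, miR-15/16, miR-29, miR-30 and miR-200 families, the miR-17-92 and miR-23/27/24 clusters, the miR-100/let-7a-2/miR-125b-1 host transcript, p53-induced miRNAs, NF-kB and inflammatory miRNAs, repressors of the EGFR-RAS pathway, colorectal oncomiRs, and hypoxia and stress miRNAs. The remaining 4 held markers of blood, of fibroblasts and mesenchyme and of liver and muscle, and entries that overlap other structured RNAs. The median log2 ratio of each list's compared members was placed among 10000 random lists of the same size, matched on mean expression in 5 bins. These percentiles describe the libraries and are not tests, and 51 list medians were computed in all. Members of a list can share a cluster or host transcript and are then not independent, unlike those of the random lists.

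Both comparisons with dose 0 share the untreated library. Sets of unchanged libraries, the shared control included, were therefore simulated 1000 times from the mean profile of the 3 libraries. This was done with counting error alone and with the added dispersion of 0.0516 seen between the treated libraries. The size rule was tested on simulated data built on the 343 miRNAs for 0.3 against 0. With counting error alone it recovered 100% of the 100 miRNAs changed 4-fold and 100% of the 100 changed 3-fold, and called 0% of 143 unchanged ones. With the added dispersion it recovered 99% and 88% and called 4.20% of the 143. The counting intervals held the true ratio for 95.3% of miRNAs with counting error alone and for 28.9% with the dispersion added.

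Positions and hosts of hairpins come from GENCODE release 29 on GRCh38, in which 1457 of the 1483 listed miRNAs and 341 of the 343 compared ones matched a gene by name. The shared sequences of the miR-7 and miR-103 entries were searched within the hairpins of that genome. Positions count from 1. Exon and intron refer to any annotated transcript of a gene on the same strand.

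Alternatives chosen beforehand were scaling by total miRNA count, median-of-ratios size factors from DESeq2 1.42.0, minimum mean CPM of 1 or 100 or none, a prior count of 5, each library's own 10 most abundant miRNAs, and an edgeR quasi-likelihood fit that joined both treated libraries into 1 class. Alternatives chosen after seeing the data were the sum of reverse-complementary entries, the authors' deposited RPM in place of TMM, and a linear correction of the log2 ratios for hairpin GC content over 341 miRNAs. That correction was made with the fit held at the median GC content and with residuals centred on the median ratio. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for the remaining steps. The deposited RPM entered that alternative alone.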

Results

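Small RNA libraries were compared from HCT116-R cells, a cetuximab-resistant derivative of the HCT116 colorectal carcinoma line. Cetuximab is an antibody that blocks the epidermal growth factor receptor (EGFR). The cells had received PA-MSHA, a Pseudomonas aeruginosa preparation that carries mannose-sensitive hemagglutinin, at 0, 0.3 or 0.4 in units of 1e9 per mL, the unit of every dose named here. The 3 libraries, 1 per dose, held 6554932, 6483942 and 5789018 miRNA counts, and 1253, 1183 and 1227 of the 1483 listed miRNAs had at least 1 read. No difference has a replicate check, so each ratio compares libraries and not conditions, and its 95% interval covers counting error only. Ratios rest on TMM-scaled counts per 1000000 (CPM) of the 343 miRNAs with a mean of at least 10 CPM.

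miR-21-5p, an oncomiR of many carcinomas, was the most abundant miRNA in every library. It took 13.1% of the counts at dose 0, 21.7% at 0.3 and 19.1% at 0.4. Its hairpin lies on chromosome 17 at 59841266 to 59841337, in an exon of VMP1 (GRCh38). miR-222-3p, which represses the cell cycle inhibitor p27, had 674221 counts at dose 0, 335095 at 0.3 and 290239 at 0.4. The 10 most abundant miRNAs, which also included miR-100-5p, miR-200c-3p, let-7a-5p, miR-31-5p, miR-191-5p, miR-92a-3p, let-7i-5p and let-7f-5p, made up 57.3% of the untreated library (Clopper-Pearson 95% interval 57.2 to 57.3). They made up 59.1% at 0.3 (59.1 to 59.1) and 57.1% at 0.4 (57.0 to 57.1).

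The first comparison asked which miRNAs differed between cells given PA-MSHA at dose 0.3 and untreated cells. miR-7-5p, a repressor of EGFR, was 56.1-fold higher (95% interval 54.2 to 58.1), with 3257 counts at dose 0 and 144621 at 0.3. miR-3529-3p was 212-fold lower, with 173975 and 649 counts, a ratio of 0.00471 (0.00435 to 0.00509). miR-103a-3p was 20.2-fold higher (18.5 to 22.1) and miR-103b 35.1-fold lower, from 9775 to 220 counts. Among the other named miRNAs, miR-129-5p was 8.80-fold higher (5.27 to 16.8), miR-192-5p 2.81-fold (2.64 to 2.99) and miR-21-5p 2.07-fold (2.07 to 2.08). miR-345-5p was 2.97-fold lower and miR-331-5p 5.32-fold lower, with ratios of 0.337 (0.321 to 0.353) and 0.188 (0.125 to 0.269).

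In all, 29 miRNAs were at least 2-fold higher and 30 at least 2-fold lower at 0.3. Simulated unchanged libraries gave on average 0.002 such calls, both directions together, with counting error alone and 14.1 with the dispersion of 0.0516. Scaling by the total miRNA count gave 13 higher and 57 lower, because it set every log2 ratio 0.32 below its TMM value, moving the median of the compared miRNAs from 0.11 to −0.22. Those that were then less than 2-fold higher included miR-21-5p, miR-200a-3p, miR-376a-3p, miR-576-3p and miR-664a-3p. A linear correction for hairpin GC content gave 30 and 26, or 34 and 21 when its residuals were centred on the median ratio.

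miR-7-5p and miR-3529-3p are listed as separate miRNAs of the same 24 bases read on opposite strands. The sequence TGGAAGACTAGTGATTTTGTTGTT occurs in the MIR7-2 hairpin on the plus strand of chromosome 15 at 88611856 to 88611879, outside annotated genes on that strand, and its reverse complement AACAACAAAATCACTAGTCTTCCA lies in MIR3529 at the same position. MIR7-1, in HNRNPK on chromosome 9, holds the miR-7-5p sequence on the minus strand at 83969811 to 83969834, overlapping an annotated exon. MIR7-3, in an intron of MIR7-3HG on chromosome 19, holds it at 4770700 to 4770723. The use of strand in the counting is not given in the sources used here, so reads of this pair cannot be told apart and both values are uncertain. Together the entries had 177232 counts at dose 0, 145270 at 0.3 and 187999 at 0.4, of which miR-7-5p held 1.84%, 99.6% and 99.0%. The scaled sum was 1.03 times the untreated value at 0.3 (1.03 to 1.04) and 1.20 times at 0.4 (1.19 to 1.21). miR-7-1-3p, the opposite arm of the MIR7-1 hairpin, had 4767, 4541 and 3867 counts, or 1.20 times the untreated level at 0.3 (1.15 to 1.253) and 0.917 times at 0.4 (0.879 to 0.957).

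The same relation joins miR-103a-3p and miR-103b, so these values are uncertain too. The 26 bases given next are the stretch found in these hairpins and are not given as the ends of the mature miRNA. TCAAGCAGCATTGTACAGGGCTATGA lies in MIR103A1, in an intron of PANK3 on chromosome 5 at 168560904 to 168560929, and in MIR103A2, in an intron of PANK2 on chromosome 20 at 3917538 to 3917563. Its reverse complement TCATAGCCCTGTACAATGCTGCTTGA lies in MIR103B1 and MIR103B2 at those positions. miR-103a-3p held 5.11% of the summed counts at dose 0, 97.5% at 0.3 and 0.50% at 0.4. The scaled sum was 1.06 times the untreated value at 0.3 (1.03 to 1.09) and 0.702 times at 0.4 (0.680 to 0.724).

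**Figure D1:**
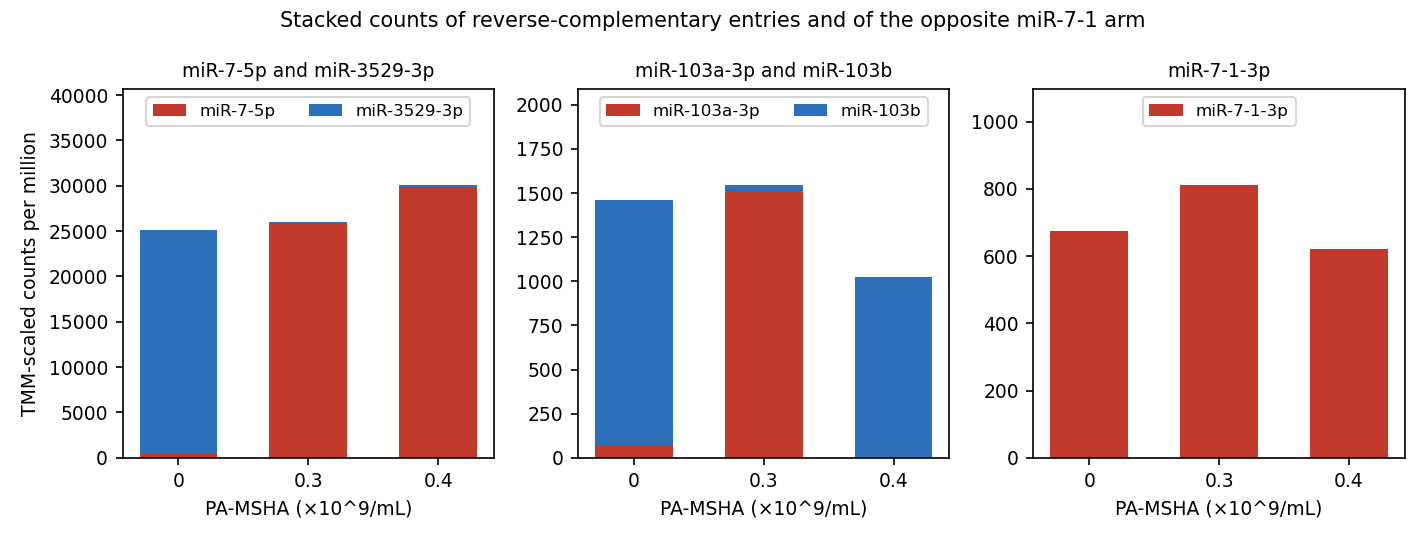
Stacked bars give TMM-scaled CPM (y axis) in the library at each PA-MSHA dose (x axis), for miR-7-5p with miR-3529-3p, miR-103a-3p with miR-103b, and miR-7-1-3p alone, with 1 library per bar and no error bars. miR-7-5p made up 1.84% of its stack at dose 0 and 99.6% at 0.3, while the summed height differed 1.03-fold.

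By group, all 9 let-7 miRNAs, a family of RAS repressors, had log2 ratios above 0 at 0.3, from 0.36 to 0.89 with a median of 0.51, at percentile 92.5 of matched random lists, and none reached 2-fold. All 5 members of the epithelial miR-200 family lay above 0, with a median of 0.56 at percentile 89.1. Only miR-200a-3p reached 2-fold among them (1.05), and miR-200c-3p turned from 0.16 to −0.16 with total-count scaling. The 3 compared of 8 p53-induced miRNAs had a median of 1.37 at percentile 99.4, with miR-192-5p at 1.49, miR-194-5p at 1.37 and miR-34a-5p at 0.79. The hairpins MIR192 and MIR194-2 share the host transcript MIR194-2HG, so these members are not independent, unlike those of the random lists. The 6 miR-15/16 family members had a median of 0.54 (percentile 92.9) and the 4 miR-30 members one of 0.69 (93.8), with none at 2-fold, but total-count scaling put miR-503-5p at −1.08. Of 6 NF-kB and inflammatory miRNAs, miR-146b-5p (1.44) and miR-21-5p (1.05) were at least 2-fold higher. That list's median was 0.12 at percentile 49.6. With total-count scaling it was −0.20 over the same 6, or −0.25 with miR-187-3p, which then passed the filter at −2.03.

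Lower medians at 0.3 were those of the 9 miR-17-92 and paralogous miRNAs, −0.21 at percentile 7.19, and of the 5 miRNAs of the miR-100/let-7a-2/miR-125b-1 host transcript, which has been linked to cetuximab resistance, −0.34 at percentile 7.26. In the host transcript list 4 members lay below 0, while the abundant miR-100-5p was at 0.15, or −0.18 with total-count scaling. miR-125b-5p can also come from MIR125B2 in MIR99AHG on chromosome 21, so it does not report on this host transcript alone. Total-count scaling put let-7a-2-3p at −1.20 and miR-125b-1-3p at −1.17, both at least 2-fold lower. The 5 miR-23/27/24 miRNAs had a median of −0.15 (percentile 13.3) and the 10 colorectal oncomiRs one of −0.04 (8.51), in which miR-21-5p was at least 2-fold higher and miR-222-3p was at −0.67, or −1.02 with the deposited RPM. Among 6 EGFR-RAS repressors, miR-7-5p alone reached 2-fold and, summed with miR-3529-3p, was at 1.03 times the untreated value. The median of 0.07 turned to −0.25 with total-count scaling. The miR-29 family median was 0.18, or −0.14 with total-count scaling, with miR-29c-3p 2.51-fold higher (2.31 to 2.74) but at a log2 ratio of 0.99 with the deposited RPM. miR-210-3p, the only compared hypoxia and stress miRNA, had a log2 ratio of −0.14.

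The next comparison set cells given dose 0.4 against untreated cells. miR-7-5p was 64.6-fold higher (62.4 to 66.9) and miR-3529-3p 83.6-fold lower, a ratio of 0.0120 (0.0114 to 0.0125), under the strand limit given for 0.3. miR-132-5p was 4.03-fold higher (3.75 to 4.35), miR-29c-3p 3.25-fold (3.002 to 3.53), miR-192-5p 3.08-fold (2.90 to 3.27) and miR-339-5p 5.65-fold (4.81 to 6.69). miR-194-5p, which shares a chromosome 11 cluster with miR-192-5p, was 6.84-fold lower, a ratio of 0.146 (0.125 to 0.169). miR-15b-5p was 5.94-fold lower (ratio 0.168, 0.157 to 0.180), miR-16-5p 2.24-fold lower (0.447, 0.443 to 0.452) and miR-222-3p 2.05-fold lower (0.487, 0.485 to 0.489). Both miR-15b and miR-16 belong to a family that represses BCL2 and cyclins.

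In all, 31 miRNAs were at least 2-fold higher and 43 at least 2-fold lower at 0.4, and total-count scaling gave the same counts. The linear GC correction gave 32 and 41, or 40 and 35 with residuals centred on the median ratio, a step that by itself set the median log2 ratio at 0.15 in place of 0.07. miR-365a-3p and miR-365b-3p are listed with identical counts of 74, 88 and 235, so the 31 hold that miRNA under 2 names.

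By group, all 4 compared miR-30 miRNAs lay above 0 at 0.4, with a median log2 ratio of 1.17 at percentile 99.6. MIR30C1 and MIR30E share the host NFYC, so these members are not independent. miR-30e-5p was 2.71-fold higher (2.30 to 3.23), miR-30c-5p 2.37-fold (2.20 to 2.55) and miR-30d-5p 2.13-fold (2.06 to 2.21). The miR-200 median was 0.60 (percentile 94.5), with miR-200a-3p 2.04-fold higher (1.97 to 2.12), or at a log2 ratio of 0.98 with the deposited RPM. The let-7 median was 0.33 (83.9), with let-7f-5p at 0.73 and let-7i-5p at −0.26. The NF-kB list had a median of 0.53 (93.9) with no member at 2-fold, though total-count scaling added miR-187-3p at −1.16, and the EGFR-RAS list one of 0.36 (80.9), with miR-30c-5p at least 2-fold higher and miR-7-5p so only when not summed with miR-3529-3p (1.20 times). The p53-induced median was 0.69 (92.4) over members that went both ways, with miR-192-5p at 1.62, miR-34a-5p at 0.69 and miR-194-5p at −2.77. miR-29 family members also went both ways, with miR-29c-3p at 1.70, miR-29b-3p at −0.40 and a median of 0.26.

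The miR-15/16 family had a median of −0.62 at percentile 3.67, with 3 of 6 members at least 2-fold lower. These were miR-15b-5p, miR-16-5p and miR-503-5p (−1.65), while miR-15a-5p was at 0.32. Colorectal oncomiRs had a median of −0.49 at percentile 1.86, with miR-222-3p the only one of 10 at least 2-fold lower, while miR-21-5p was at 0.54 and miR-96-5p and miR-183-5p at 0.39. The miR-100 host transcript list had a median of −0.67 at percentile 4.62, in which let-7a-2-3p was 3.29-fold lower (ratio 0.304, 0.269 to 0.343) and miR-125b-1-3p had a ratio of 0.4995 (0.468 to 0.533), which total-count scaling put just short of 2-fold. In the same list miR-100-5p was at −0.15 and miR-125b-5p, which can also come from MIR125B2 on chromosome 21, at 0.61. All 5 miR-23/27/24 miRNAs lay below 0, with a median of −0.53 (7.53) and none at 2-fold. The miR-17-92 median was −0.36 (9.98), and miR-210-3p was at 0.43.

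**Figure D2:**
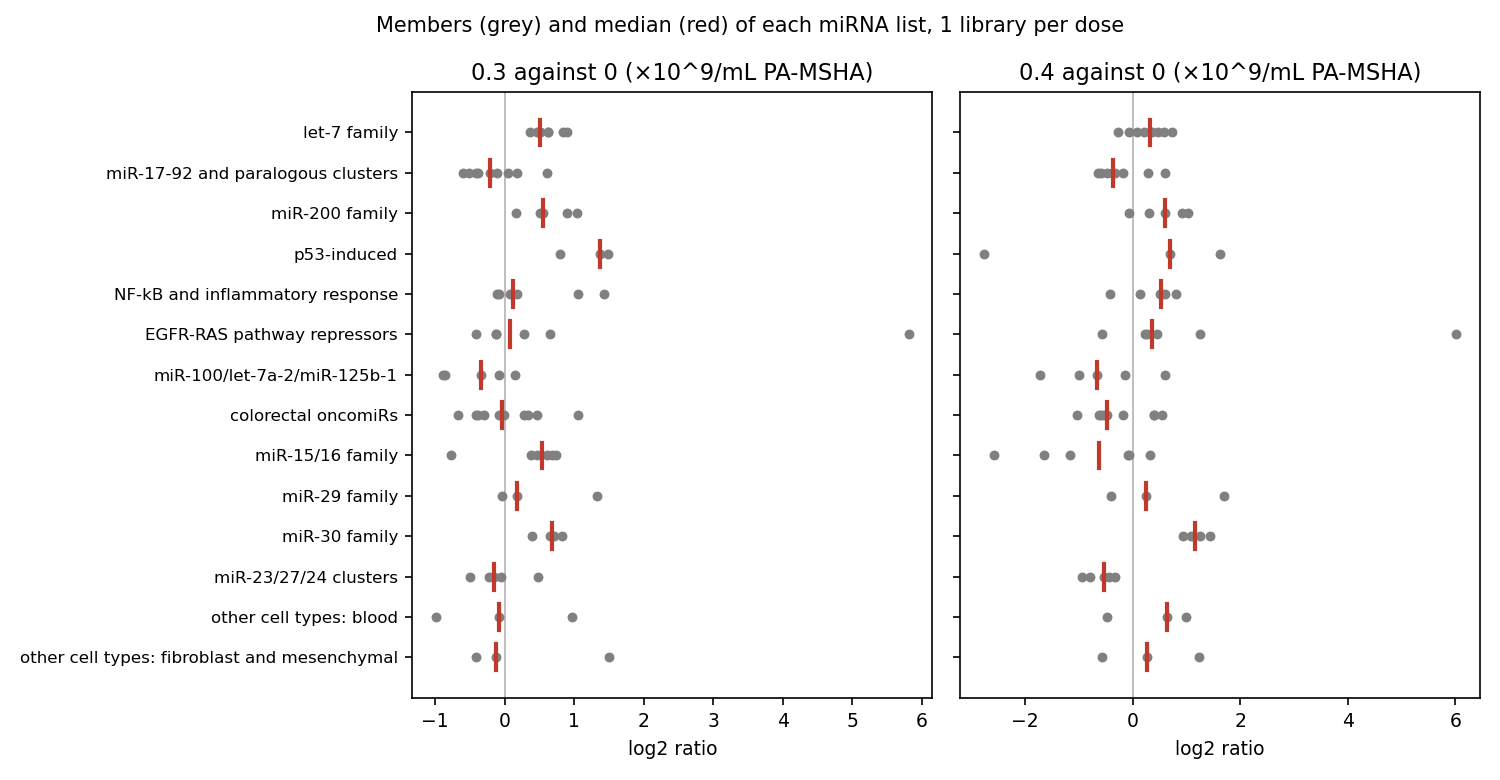
Grey points give the log2 ratio (x axis) of each compared miRNA and red bars the median of its list (y axis), for 0.3 against 0 on the left and 0.4 against 0 on the right, in the 14 lists with at least 3 compared members. The miR-30 median lay at 0.69 and 1.17 and the miR-15/16 median at 0.54 and −0.62, while at 0.3 the NF-kB, EGFR-RAS and miR-29 medians fall below 0 with total-count scaling.

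Markers of other cell types were few among the compared miRNAs. miR-10b-5p, on the fibroblast and mesenchymal list, was 2.84-fold higher at 0.3 (2.73 to 2.95) and 2.34-fold at 0.4 (2.25 to 2.43), while miR-143-3p was at log2 ratios of −0.41 and −0.56 and miR-145-5p at −0.12 and 0.27. That list's median was −0.12 at 0.3 and 0.27 at 0.4. The blood list had 3 compared members, with miR-451a at 0.97 and 0.99, miR-486-5p at −0.98 (−1.30 with total-count scaling) and −0.49, and a median of −0.08 and 0.63. Muscle miR-499a-5p was at 0.87 and 0.85 and was the only compared member of the liver and muscle list. miR-664a-3p, whose hairpin overlaps the small nucleolar RNA SNORA36B, was the only compared member of the list of entries that overlap other structured RNAs, at 1.05 and 0.92.

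The third question was which miRNAs stood apart from the untreated library at both doses. Those higher at both doses were led by miR-7-5p, miR-129-5p, miR-548ap-3p, miR-26b-3p, miR-132-5p, miR-192-5p, miR-29c-3p, miR-376c-3p, miR-576-3p and miR-376a-3p. miR-129-5p, with 15, 108 and 124 counts at the rising doses, had log2 ratios of 3.14 and 3.18. miR-132-5p had 925, 2156 and 3301 counts and miR-29c-3p 799, 1590 and 2300. Those lower at both doses were led by miR-3529-3p, miR-331-5p, miR-1343-5p, miR-188-5p, miR-345-5p, miR-3187-3p, miR-1306-5p, miR-548ad-5p, miR-548ae-5p and miR-589-3p. miR-345-5p had 7942, 2119 and 1759 counts, was 2.97-fold lower at 0.3 and 3.99-fold lower at 0.4, and has its hairpin outside annotated genes on its strand of chromosome 14 at 100307859 to 100307956. miR-548ad-5p and miR-548ae-5p are listed with identical counts of 188, 53 and 47 and count as 2 of the lower miRNAs.

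In each direction 19 miRNAs were at least 2-fold apart at both doses, against 2.62 higher and 3.76 lower for independent lists of these sizes. Sets of unchanged libraries, simulated with a shared control drawn like the others, gave 0 and 0 with counting error alone. They gave 1.70 and 0.80 with the dispersion of 0.0516. Only miR-103a-3p and miR-194-5p were called in opposite directions. Across miRNAs, which are not independent replicates, the log2 ratios at both doses had a Pearson correlation of 0.69, a Spearman correlation of 0.72 and a covariance of 0.67, and 75.2% had the same sign. The simulated values were 0.45, 0.40 and 0.0075 with counting error alone, and 0.50, 0.48 and 0.118 with the dispersion. A larger dispersion of 0.103, from the edgeR fit of both treated libraries as 1 class, was not simulated. The simulated overlaps and correlations may therefore be too low. Without miR-7-5p and miR-3529-3p the observed values were 0.59, 0.71 and 0.42. The untreated library cannot be split, so how much of the excess comes from it, up to all of it, cannot be told. In the simulations the control was no noisier than the treated libraries. With total-count scaling 10 of the 19 higher and 19 of the 19 lower miRNAs were still called, among 10 higher and 29 lower.

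**Figure D3:**
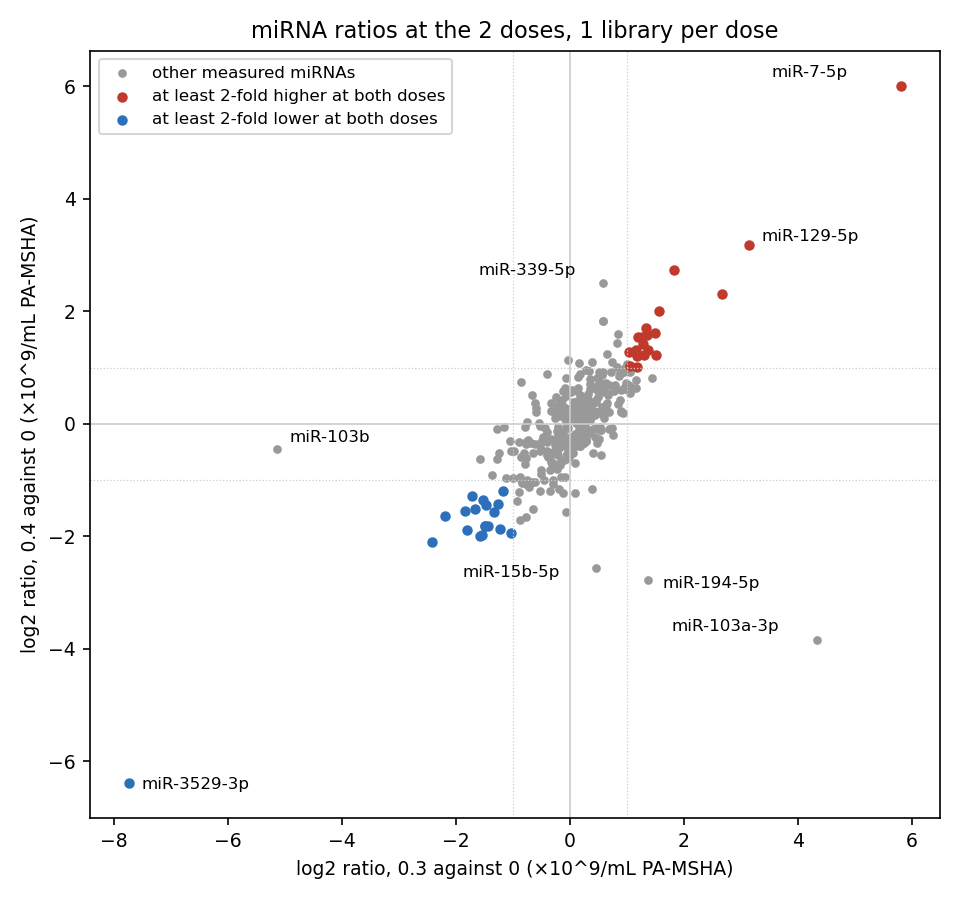
Each point is a compared miRNA, with its log2 ratio of 0.3 against 0 on the x axis and of 0.4 against 0 on the y axis. The 19 red points were at least 2-fold higher and the 19 blue points at least 2-fold lower at both doses, and miR-103a-3p and miR-194-5p lie at the lower right, at 4.34 and 1.37 on the x axis.

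The last comparison set the treated libraries against each other. At 0.4, miR-194-5p was 17.7-fold lower than at 0.3, a ratio of 0.0566 (0.0487 to 0.0652), with 3124 counts at 0.3 and 197 at 0.4. miR-15b-5p was 8.19-fold lower (ratio 0.122, 0.114 to 0.130), miR-16-5p 2.91-fold lower (0.343, 0.340 to 0.347) and miR-421 2.80-fold lower (0.357, 0.317 to 0.400), with miR-421 at 0.339 times dose 0 (0.302 to 0.378). miR-339-5p was 3.76-fold higher (3.24 to 4.39), miR-1268a 3.04-fold (2.68 to 3.46) and miR-1268b 2.45-fold (1.77 to 3.50). Whether miR-1268a and miR-1268b share reads was not checked. Entries with a reverse-complementary partner also stood apart, with miR-103a-3p 290-fold lower and miR-103b 25.8-fold (22.6 to 29.7) and miR-3529-3p 2.54-fold (2.32 to 2.78) higher. In all, 11 miRNAs were at least 2-fold higher and 8 at least 2-fold lower, and total-count scaling gave 32 and 5. The 11 hold miR-365a-3p and miR-365b-3p, which have identical counts and count as 2.

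All 6 miR-15/16 family members were lower at 0.4 than at 0.3, with a median log2 ratio of −0.85 at percentile 0.01, and −0.53 with total-count scaling, which put miR-15a-5p at 0.03. MIR15B and MIR16-2 share the host SMC4 and MIR424 and MIR503 the host MIR503HG, so these members are not independent. The miR-30 family had a median of 0.60 at percentile 99.6 and the miR-23/27/24 clusters one of −0.57 at percentile 2.02, with no member of either at 2-fold. With total-count scaling these medians were 0.92 and −0.25, and miR-30d-5p at 1.02, miR-125b-5p at 1.01 and miR-150-5p at 1.03 reached 2-fold. The EGFR-RAS list had a median of 0.28, miR-29 of 0.30, the blood list of 0.50 and miR-210-3p a value of 0.58, each above 0 under both scalings. The remaining medians lay below 0 with TMM and above 0 with total-count scaling. They were −0.30 and 0.03 for let-7, −0.07 and 0.25 for miR-17-92, −0.22 and 0.10 for miR-200, −0.11 and 0.22 for the p53-induced list, and −0.12 and 0.20 for the NF-kB list, or 0.56 with miR-187-3p added. Those of the miR-100 host transcript were −0.29 and 0.03, of the oncomiRs −0.30 and 0.02 and of the fibroblast list −0.16 and 0.17. miR-499a-5p stood at −0.01 and 0.31 and miR-664a-3p at −0.13 and 0.19.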

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

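The tests of summed reverse-complementary entries, of scaling without the most abundant miRNAs, of miR-15b-3p alone and of the miR-15/16 family summed with and without miR-16-5p were chosen after the values were seen; the tests of miR-7-1-3p, of GC content and of the opposite arms were set before. miR-103a-3p stood out because its log2 ratio was 4.34 at 0.3 and −3.84 at 0.4, opposite directions against the same untreated library. miR-194-5p did likewise, with 1.37 at 0.3 and −2.77 at 0.4. With 1 library per dose neither difference between doses was tested.

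miR-7-5p was 56.1- and 64.6-fold higher at the treated doses while miR-3529-3p, its reverse complement, was 212- and 83.6-fold lower, and miR-103a-3p traded places with miR-103b without following the dose. More miR-7 made from MIR7-1 is argued against by its opposite arm, miR-7-1-3p, at 1.20 times the untreated level at 0.3 and 0.917 times at 0.4. MIR7-2 and MIR7-3 are left open by that arm, since miR-7-2-3p had 0, 5 and 1 counts. Reads of the same sequence assigned to either entry may account for both pairs, since the miR-7 sum stayed at 1.03 and 1.20 times the untreated value and the miR-103 sum at 1.06 and 0.702 times. miR-3529-5p, with 1, 1 and 0 counts, gave no sign of its own hairpin in the library where miR-3529-3p had 173975, but a real exchange of these miRNAs would leave the same sums and stays open, and why the assignment would differ between libraries was not tested.

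miR-16-5p, miR-15b-5p and miR-194-5p were among 7 miRNAs at least 2-fold lower at 0.4 than in both other libraries, and the causes for miR-421, miR-2277-3p and miR-3909 were not tested. Counting of miR-16-5p reads under other listed members of its family is argued against, because the summed family was itself 0.487 times dose 0 and 0.368 times 0.3, but the same for miR-15b-5p stays open, since the family without miR-16-5p was 0.783 times dose 0 and 0.532 times 0.3. For miR-15b, less hairpin output as the whole explanation is argued against by miR-15b-3p, at 0.935 times dose 0 (0.790 to 1.11) and 0.709 times 0.3 (0.5996 to 0.837). For the 3 miRNAs together the median opposite arm was 0.935 times dose 0 and 1.03 times 0.3, above the limit of 0.75 set beforehand. However, the latter is miR-16-2-3p with 27 and 31 counts (0.594 to 1.79), at 0.548 times dose 0 (0.345 to 0.854). The requirement that the interval also clear the limit was therefore added after the values were seen. miR-16-5p also comes from MIR16-1, and no opposite arm of that hairpin was included. Hairpin output stays open for miR-16 and for miR-194, whose miR-194-3p had 2, 1 and 11 counts, although the cluster partners miR-15a-5p and miR-192-5p were at 1.2497 and 3.08 times dose 0 and 0.816 and 1.10 times 0.3, while stability, end variants and the assignment of miR-194-5p reads were not tested and a treatment effect at 0.4 stays open.

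With total-count scaling 13 miRNAs were at least 2-fold higher and 57 lower at 0.3, a lean that is absent with TMM scaling (29 and 30). The share of counts taken by the 10 most abundant miRNAs is argued against as its cause, since scaling by the total without them still gave 3.25 lower miRNAs for each higher one. GC bias between the libraries stays open and cannot be told apart from other causes, because the Spearman correlation of hairpin GC content with the log2 ratio across 341 miRNAs was −0.28, between the limits set beforehand of −0.3 for and −0.1 against it. A lower output of many miRNAs at 0.3, which would need a spike-in to measure, is also open and was not tested.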

How the results depend on the processing

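The deposited RPM, the summed reverse-complementary entries and the 2 forms of GC correction as alternatives for the counts were chosen after seeing the data. No paired analysis was possible because each dose has 1 library and the doses share only replicate number 1. Counts are given as higher then lower. Total-count scaling gave 13 and 57 at 0.3 against 0, 32 and 5 at 0.4 against 0.3, and 10 and 29 at both doses. The deposited RPM gave 12 and 58 at 0.3 against 0, 27 higher at 0.4 against 0.3, and 9 and 35 at both doses. Both differ from TMM by 1 factor per library, apart from a few miRNAs at the filter, and which scaling is right was not tested. A minimum mean CPM of 1 gave 62 and 78 at 0.3 against 0, 73 and 96 at 0.4 against 0, 33 and 20 between treated doses, and 35 and 49 at both doses. No filter gave 67 and 83, 84 and 106, 41 and 25, and 35 and 51, in the same order. A minimum of 100 gave 14 and 8, 15 and 22, 3 higher, and 9 and 5, since fewer miRNAs are compared. Each library's own 10 most abundant miRNAs held 57.9%, 59.7% and 58.2%, by construction at least the shared 10. Median-of-ratios factors, a prior count of 5, the GC corrections and the summed entries left every count within 1.5 times the reported one, and at both doses the summed entries kept 18 of 19 in each direction. The edgeR quasi-likelihood fit of both treated libraries as 1 class, with 1 residual degree of freedom and the spread between doses in place of replicates, called 16 higher and 20 lower of 343 at adjusted p under 0.05 and 71 at unadjusted p under 0.05. It shared 12 of the 19 higher and 18 of the 19 lower miRNAs with the size rule, and 1 of its 16, miR-103a-3p, lay in opposite directions at the treated doses. The correlation of ratios at both doses lay between 0.53 and 0.75 over 8 alternatives. Of 399 list medians recomputed, 286 stayed within counting error and 113 moved, as did 153 of 930 log2 ratios of named miRNAs. The 930 include the filter alternatives, which cannot move a log2 ratio. Total-count scaling moved 30 of 51 list medians and 55 of 117 log2 ratios, and the deposited RPM moved 36 and 69 of them. Named miRNAs that turned sign were low in size, such as miR-100-5p at 0.3, from 0.15 to −0.18 with total-count scaling. Depth limits miRNAs such as miR-129-5p, with 15 counts at dose 0, far more than miR-21-5p.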

Other observations

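The imprinted miRNA cluster on chromosome 14, between 101022066 and 101066801 on the plus strand (GRCh38), was chosen after the values of 11 genomic miRNA clusters had been seen. Its 6 compared members, miR-376a-3p, miR-376b-3p, miR-376c-3p, miR-379-5p, miR-381-3p and miR-411-5p, all had log2 ratios above 0 at both doses. Their median was 1.18 at 0.3 and 1.31 at 0.4, each at percentile 99.99 of matched random lists. Neighbours in a cluster are not independent, unlike members of the random lists, and both comparisons share the untreated library. With the choice made after seeing the values, these percentiles cannot show how unusual the cluster is. miR-376c-3p had 309, 627 and 820 counts at 0, 0.3 and 0.4, and miR-376b-3p 181, 373 and 399. The 4 that were at least 2-fold higher at each dose were the miR-376 members and miR-381-3p, while miR-379-5p was at 0.43 and 0.23 and miR-411-5p at 0.96 and 0.63. With total-count scaling the median at 0.3 was 0.86, and miR-376a-3p at 0.88 and miR-381-3p at 0.84 were less than 2-fold higher. After a linear correction for hairpin GC content the medians were 0.88 and 1.17.

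Among 18 arrangements of entries on opposite strands of the same locus, shares moved far less outside the miR-7 and miR-103 loci. miR-24-3p held 70.8%, 64.3% and 63.5% of its sum with miR-3074-5p at 0, 0.3 and 0.4, and miR-374c-3p held 32.02%, 34.2% and 55.9% of its sum with miR-374b-5p. The scaled sum of miR-374c-3p and miR-374b-5p was 1.22 times dose 0 at 0.4 (1.17 to 1.27). At the miR-423 locus the arms were counted on opposite strands in every library. There miR-423-5p held 0.965%, 0.300% and 0.793% of its sum with miR-3184-3p. By contrast, miR-423-3p held 99.998%, 100% and 99.997% of its sum with miR-3184-5p. Whether strand was used in the counting could not be tested.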
